A study of Mus musculus with 24 samples.

How the data were processed

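Messenger RNA was sequenced in 24 libraries of C2C12, an established mouse myoblast line that stops dividing and fuses into multinucleated myotubes when serum is lowered. The libraries were made with a stranded kit that selects polyadenylated RNA. Per the labels, the libraries fall into 6 groups of 4: day 0 myoblasts, day 7 myotubes, myotubes given 100 µM dexamethasone for 24 h or for 72 h, and myotubes kept for 24 h or for 72 h in medium with the vehicle, 1% ethanol. The treated and vehicle groups were therefore collected at day 8 and day 10. Day 0 myoblasts were kept in 10% fetal bovine serum and all other groups in 2%. Dexamethasone is a synthetic glucocorticoid used to induce atrophy of muscle cells. The labels name ethanol for the vehicle medium alone and do not say whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

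Per the submitters' processing notes, the genome build was GRCm39 and the tools included Salmon, DESeq and kallisto 0.51.1, with no role or order given. One deposited table holds log2-scale values that the authors normalised between libraries by a method the labels do not state. These values run from −2.33 to 20.06 and are not counts, although the design had assumed normalised counts. They are also shrunken toward each gene's mean. The slope of the differences in this table on the log2 differences of TPM was 0.58 for differentiation, 0.54 for dexamethasone at either time, and 0.36 to 0.37 for the comparisons between vehicle or untreated groups. Log2 differences from this table therefore understate fold changes. The other deposited table holds TPM computed by the authors, a length-scaled abundance that sums to 1000000 in every library. Neither table keeps the sequencing depth, so the depth per library is unknown and no counting interval can be given. Both tables list 48544 genes, of which 18188 were at 0 TPM in every library. Between 12428 and 13030 genes per library reached a TPM of 1. Gene symbols were taken by identifier from a reference annotation of an older build, which matched 48291 of the genes, and no coordinates were used.

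Genes were tested with limma 3.58.1 in R 4.3.3 (limma-trend, empirical Bayes with a mean-variance trend) on the deposited log2 values as they stand. A gene entered the test when 2 to the power of its value was at least 10 in at least 4 libraries, which left 16257 genes. All 24 libraries were fitted together with 1 mean per group and no covariate. The comparisons were day 7 myotubes minus day 0 myoblasts, dexamethasone minus vehicle at 24 h and at 72 h, the difference between these responses (72 h minus 24 h), vehicle 24 h minus day 7 myotubes, and vehicle 72 h minus vehicle 24 h. Adjusted p-values are Benjamini-Hochberg values over the genes tested within a comparison, and genes below 0.05 were counted as higher or lower. Levels in the text are mean TPM ± SD (n = 4), and folds are ratios of mean TPM, given where the lower mean is at least 0.5. The tests were repeated on the deposited TPM as log2(TPM + 0.1) for 15250 genes with a TPM of at least 0.5 in at least 4 libraries.

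The tests were also tested on simulated data, drawn as independent normal noise around each gene's overall mean with its spread within groups. Known differences were added to 50 genes of each size. Links between same-numbered libraries and material shared between libraries were not simulated. Differences of 1 on the log2 scale of the deposited table were found for 84% to 90% of the genes and differences of 0.5 for 56% to 60%, none with the wrong sign. Between 5 and 9 unchanged genes were called in each simulated comparison.

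Before the data were examined, the groups, comparisons, tests, alternatives, 29 gene lists and the rule for named genes were fixed. The lists are glucocorticoid receptor targets, steroid receptors and steroid handling, ubiquitin ligases of muscle atrophy, proteasome subunits, autophagy and lysosome, sarcomere, myogenic regulators and fusion, satellite and reserve cell markers, cell cycle, excitation-contraction coupling, neuromuscular junction and denervation, oxidative phosphorylation, glycolysis and glycogen, fatty acid oxidation, insulin and IGF signalling, myostatin and TGF-beta signalling, extracellular matrix, inflammatory genes, circadian clock, integrated stress response, cholesterol synthesis, xenobiotic and oxidative stress, heat shock, cytosolic ribosomal proteins, adipocyte, osteoblast, fibroblast and smooth muscle markers, and mitochondrially encoded genes. C2C12 is a clonal line, so the marker lists are read for cells that did not fuse or took another fate. The filter left fewer members of some lists to test, such as 10 of 16 adipocyte markers, 8 of 14 osteoblast markers and 20 of 27 inflammatory genes. Each list was compared with the other tested genes by camera (limma) with a preset correlation between genes of 0.01, adjusted over the 29 lists of a comparison, and again with an estimated correlation. The rule for named genes takes the 10 largest rises and the 10 largest falls (5 each for the last 3 comparisons). These needed an adjusted p below 0.05, a mean value of at least 100 in the higher group on the linear scale of the log2 table, no overlap between the 4 libraries of each group (not asked for the difference between responses) and a symbol that is not a predicted-gene or clone name. It adds up to 4 members per list with the largest change, or the most abundant members where fewer than 2 passed. It always includes Nr3c1, Fkbp5, Tsc22d3, Klf15, Fbxo32, Trim63, Mstn, Igf1, Myod1, Myog, Pax7, 6 myosin heavy chain genes, Ckm, Acta1, Mki67, Foxo1 and Foxo3. Some named genes have near-identical relatives between which short reads are divided uncertainly: Prl2c2 and Prl2c3, Orm1 and Orm3, Serpina3n and Serpina3m, Hspa1a and Hspa1b, Mt1 and Mt2, and the myosin heavy chains.

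Shares of myosin heavy chain TPM and of mitochondrially encoded TPM were compared by two-sided exact permutation tests over the 70 assignments of 4 and 4 libraries, whose smallest p is 0.0286. Gene-wise correlations between effects were tested by permuting libraries within a comparison. Replicate numbers are shared between groups without a stated meaning. The deviations of same-numbered libraries from their group means correlated at 0.14 to 0.21 between day 0 and day 7, at 0.2 to 0.39 between dexamethasone and vehicle at 24 h and at 0.12 to 0.34 at 72 h. Every such pair lay over 0.1, so the numbers were taken to pair these libraries, from the data and not from the labels. Between day 7 and vehicle 24 h (−0.01 to 0.49) and between the vehicle times (−0.25 to 0.56) this did not hold. The fit was kept without a block, as fixed in advance. For the comparisons whose libraries were taken as pairs, values with the replicate number as a block are given where they change a call or move a count by over 1.5 times. For the comparisons of vehicle groups they are given only in part. The alternatives fixed in advance were another filter or none, quantile normalisation, the TPM table, robust empirical Bayes, a replicate block, a fit of the compared groups alone and leaving out each library in turn. The fits to counts by edgeR and DESeq2 and the pseudocounts 0.5 and 8 were planned for counts and were not run. Chosen after the data were seen were a TPM pseudocount of 1, exact sign changes of myosin shares within the pairs, leaving out both 72 h replicate 1 libraries, which held transcripts typical of each other's treatment, and leaving out all 6 replicate 1 libraries. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Results for some named genes are not reported here.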

Results

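Polyadenylated RNA was measured in 24 libraries of C2C12 cells: 4 each of day 0 myoblasts, day 7 myotubes, myotubes treated with 100 µM dexamethasone for 24 h or for 72 h, and myotubes in vehicle medium with 1% ethanol for 24 h or for 72 h. The sequencing depth is unknown, and between 12428 and 13030 genes per library reached a TPM of 1. Unless another test is named, p-values are adjusted p-values from limma over 16257 genes, and levels are mean TPM ± SD (n = 4).

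Day 7 myotubes were compared with day 0 myoblasts to describe differentiation. The change from 10% to 2% serum is part of this comparison and cannot be told apart from it. Genes of the contractile apparatus rose and cell cycle genes fell. Mylpf, a fast muscle myosin light chain, rose 69-fold, from 133 ± 20.5 to 9208 ± 504 TPM (adjusted p = 1.49e-15). Myl4, an embryonic myosin light chain, rose 126-fold, from 18 ± 4.24 to 2271 ± 266 TPM (adjusted p = 3.78e-16). Mki67, a proliferation marker, was 13-fold lower, at 3.43 ± 2.42 against 44.6 ± 5.6 TPM (adjusted p = 5.41e-06). Ccnd1, a cyclin of the G1 phase, was 12.5-fold lower, at 11.2 ± 10.1 against 140 ± 21.2 TPM (adjusted p = 2.71e-07).

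All 44 tested sarcomere genes rose and none fell, among them Tnnc1 (63.5-fold), Acta1 (33.8-fold), Myh1 (46.1-fold) and Myh3 (21.8-fold). The list had a camera adjusted p = 4.34e-29, and adjusted p = 0.164 with an estimated correlation. All 35 cell cycle genes fell, Cdc6 by a factor of 14.6 (camera adjusted p = 4.18e-13, adjusted p = 0.539 with an estimated correlation). Of 23 genes of excitation-contraction coupling, which links the action potential to calcium release, 19 rose and 1 fell. The calcium buffer Casq2 reached 467 ± 71.3 TPM from 6.94 ± 1.82. The camera adjusted p was 1.4e-10, and adjusted p = 0.233 with an estimated correlation. Among 19 myogenic regulators and fusion genes, 13 rose and 4 fell (camera adjusted p = 0.000181, adjusted p = 0.233 with an estimated correlation). Myog, a transcription factor of terminal differentiation, rose 17.4-fold to 1154 ± 164 TPM, the fusion gene Mymx rose 31-fold and the transcription factor Mef2c 32.1-fold. Myod1, the determination factor, stood at 128 ± 9.36 TPM against 136 ± 33.9 in myoblasts (adjusted p = 0.855). Of 19 genes of the neuromuscular junction, 14 rose and 2 fell, and the fetal acetylcholine receptor subunit Chrng rose 16-fold (camera adjusted p = 2.57e-05, adjusted p = 0.233 with an estimated correlation). Pax7, a satellite cell factor, was 2.31-fold lower at 2.19 ± 0.422 TPM (adjusted p = 0.00219).

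Autophagy and lysosome genes had 23 of 34 higher and 3 lower, with Map1lc3a 3.5-fold and the protease Ctsd 2.78-fold higher (camera adjusted p = 0.00037, adjusted p = 0.233 with an estimated correlation). Oxidative phosphorylation had 27 of 39 higher and 2 lower, 29 and 2 adjusted over the list alone, or 26 and 4 by TPM, with the muscle subunit Cox6a2 154-fold higher (camera adjusted p = 0.00037, adjusted p = 0.724 with an estimated correlation). Proteasome subunits had 18 of 33 higher and 2 lower, Psmc3 1.57-fold (camera adjusted p = 0.0155, adjusted p = 0.724 with an estimated correlation). Extracellular matrix genes had 16 of 32 higher and 3 lower, or 17 and 3 adjusted over the list alone. Postn, a matricellular protein, rose 20.9-fold, whereas the crosslinking enzyme Loxl2 was 5.71-fold lower (camera adjusted p = 0.0465, 0.117 after quantile normalisation, 0.0646 with the replicate number as a block and adjusted p = 0.724 with an estimated correlation). Cholesterol synthesis genes had 13 of 20 lower and none higher, the sterol transport gene Stard4 3.74-fold (camera adjusted p = 0.00715, adjusted p = 0.724 with an estimated correlation). Of the ubiquitin ligases of muscle atrophy, 9 of 20 were higher and 6 lower (camera adjusted p = 0.255), with Trim63 44.1-fold higher and Fbxo32 1.87-fold higher (adjusted p = 0.00068).

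The remaining lists were not called by camera, and no list passed in differentiation with an estimated correlation. Members higher and lower were 2 and 10 of 16 satellite and reserve cell markers (1 and 10 by TPM, adjusted p = 0.075, and 0.0262 for a fall with the replicate number as a block), 6 and 1 of 11 fibroblast markers (0.114), 0 and 4 of 10 adipocyte markers (0.105), 1 and 5 of 8 osteoblast markers (0.255, with 2 and 5 under the block) and 2 and 1 of 9 smooth muscle markers (0.492, with 2 and 3 under the block). They were 8 and 3 of 21 fatty acid oxidation genes (0.183), 9 and 7 of 25 glycolysis genes (0.583), 9 and 3 of 24 insulin and IGF signalling genes (0.255) and 6 and 7 of 21 TGF-beta signalling genes (0.918). Inflammatory genes had 5 and 8 of 20 (0.368, and 3 and 8 of 19 by TPM), circadian clock genes 4 and 1 of 16 (0.533), the integrated stress response 2 and 6 of 19 (0.271), xenobiotic genes 3 and 10 of 20 (0.175) and heat shock genes 3 and 7 of 15 (0.368). Ribosomal proteins had 1 and 8 of 34, or 0 and 6 adjusted over the list alone (0.271), and mitochondrially encoded genes 2 and 0 of 13, with 0 adjusted over the list alone (0.809). Glucocorticoid receptor targets had 7 and 3 of 30 (0.492), and steroid receptors and steroid handling 3 and 4 of 10 (0.492, and 1 and 4 of 9 by TPM). Median and mean differed in sign for the receptor targets (median −0.06, mean 0.2), steroid handling (−0.2 and 0.07), glycolysis (−0.04 and 0.35) and heat shock (−0.15 and 0.04), where camera's direction was up for the receptor targets and for glycolysis and down for the others.

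In all, 9797 genes differed between myotubes and myoblasts, 4956 higher and 4841 lower, and 2309 of them by at least 1 on the log2 scale of the deposited table. The largest falls included those of Prl2c2 (226-fold), Prl2c3 (151-fold) and the neurofilament gene Nefl (145-fold), and the largest rises for which a fold can be given included Cav3 (221-fold), Ctrb1 (210-fold) and Ankrd2 (161-fold). TPM called 8896 genes, 3936 higher and 4960 lower, and their median over all genes with a mean above 1 TPM was shifted by −0.11 on the log2 scale. Nr3c1, the glucocorticoid receptor gene, was at 23.7 ± 3.3 TPM in myotubes and 30.3 ± 5.44 in myoblasts (adjusted p = 0.0817), and without day 0 replicate 2 this difference passed (adjusted p = 0.028).

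**Figure D1:**
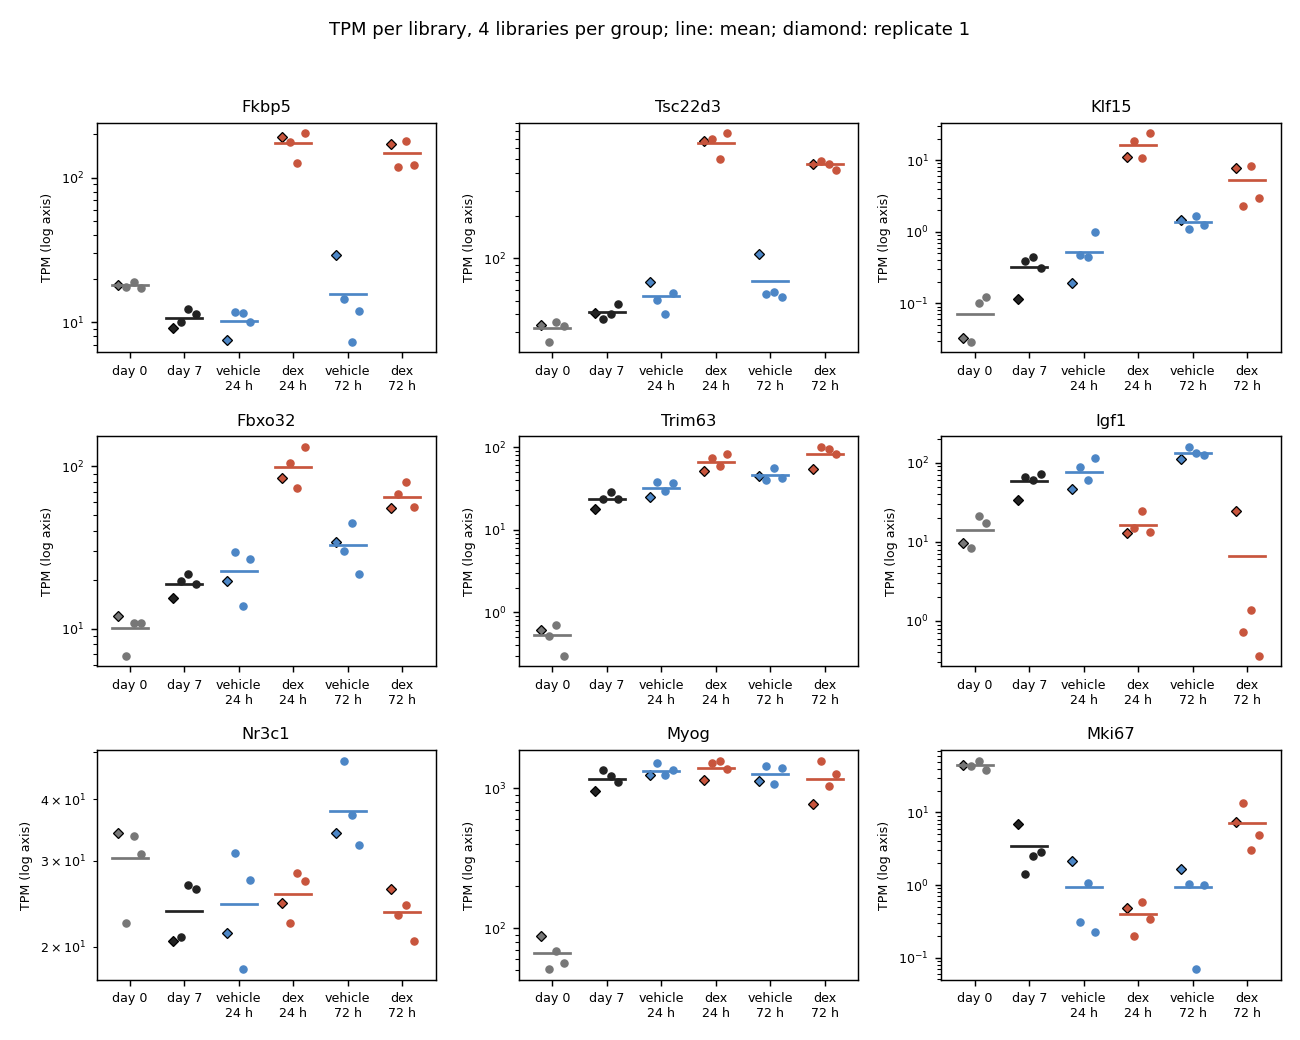
TPM of 9 genes in every library (log axis), with 1 point per library, a line at the mean of each group of 4 and diamonds for replicate 1. Fkbp5 averaged 175 TPM with dexamethasone at 24 h and 149 at 72 h against 10.2 and 15.7 with vehicle, and the dexamethasone 72 h replicate 1 library held 24.2 TPM of Igf1.

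The comparison of dexamethasone with vehicle at 24 h asked for the early response of myotubes to the glucocorticoid. Known direct targets of the glucocorticoid receptor rose strongly. Fkbp5, a co-chaperone that restrains the receptor, rose 17.1-fold, from 10.2 ± 1.96 to 175 ± 34.6 TPM (adjusted p = 4.97e-10). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose 12.2-fold to 658 ± 112 TPM (adjusted p = 2.14e-11). Klf15, a transcription factor of catabolic metabolism, rose 30.5-fold to 16.1 ± 6.4 TPM (adjusted p = 2.4e-08). The atrophy ligase Fbxo32 (atrogin-1) rose 4.38-fold, from 22.5 ± 7.19 to 98.7 ± 25.6 TPM (adjusted p = 1.62e-07), and Trim63 (MuRF1) rose 2.06-fold to 66.6 ± 13.5 TPM (adjusted p = 0.000205).

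Of 30 glucocorticoid receptor targets, 25 rose and 1 fell (camera adjusted p = 1.32e-22). This was the 1 list that kept its call with an estimated correlation at 24 h (adjusted p = 0.0344). Among 20 ubiquitin ligases of muscle atrophy, 7 rose and none fell, or 9 and 0 adjusted over the list alone, Cblb 3.1-fold (camera adjusted p = 0.000576, adjusted p = 0.488 with an estimated correlation). Foxo3, a transcription factor that drives such ligases, rose 1.87-fold to 36.5 ± 6.25 TPM (adjusted p = 6.31e-05). Of 16 adipocyte markers listed, 10 passed the filter for testing, with 7 higher and none lower (camera adjusted p = 3.38e-05, adjusted p = 0.169 with an estimated correlation). The fatty acid binding protein Fabp4 was at 38 ± 9.31 against 0.145 ± 0.128 TPM and the transcription factor Cebpa was 5.5-fold higher. Among the largest rises, Serpina3n, a protease inhibitor, reached 312 ± 162 TPM from 0.0468 ± 0.0272, Lbp, which binds bacterial lipopolysaccharide, rose 110-fold and Orm1, an orosomucoid, 80.7-fold. Of the steroid receptor and steroid handling list, 5 of 10 rose and 1 fell (camera adjusted p = 0.0296, adjusted p = 0.525 with an estimated correlation), including the 2.95-fold higher H6pd, which supplies the cofactor for glucocorticoid reactivation. Nr3c1 was at 25.6 ± 2.64 TPM with dexamethasone and 24.5 ± 5.87 with vehicle (adjusted p = 0.956).

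Extracellular matrix genes had 6 of 32 higher and 13 lower, 6 and 16 adjusted over the list alone, or 4 and 8 of 31 by TPM (camera adjusted p = 0.00355, adjusted p = 0.606 with an estimated correlation). The metalloproteinase inhibitors Timp3 and Timp1 were 13.9-fold and 4.7-fold lower, and Fbn1, a microfibril protein, was 4.97-fold lower. Among 20 inflammatory genes, 3 rose and 10 fell, or 3 and 12 adjusted over the list alone, and the chemokine Cxcl12 was 2.24-fold lower. That list had a median of −0.38 and a mean of 0 on the log2 scale (camera adjusted p = 0.0116 for a fall, adjusted p = 0.354 with an estimated correlation). Igf1, a growth factor for muscle, was 4.73-fold lower at 16.3 ± 5.33 against 77.2 ± 30.1 TPM (adjusted p = 0.0037), and Igfbp4, which binds it, 14.6-fold lower. Deptor, an inhibitor of mTOR, rose 2.91-fold. Insulin and IGF signalling as a list had 6 higher and 4 lower, and TGF-beta signalling also 6 higher and 4 lower, but 6 and 1 of 20 by TPM.

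Sarcomere genes had 8 of 44 higher and none lower, or 7 adjusted over the list alone, Myh1 1.77-fold (camera adjusted p = 0.0211, adjusted p = 0.606 with an estimated correlation). Excitation-contraction coupling had 6 of 23 higher and 1 lower, or 10 and 1 with the replicate number as a block (camera adjusted p = 0.00468, adjusted p = 0.606 with an estimated correlation). Myogenic regulators had 4 of 19 higher and smooth muscle markers 3 of 9, with none lower (camera adjusted p = 0.0767 and 0.0657, and 0.0411 and 0.0351 with the block). With an estimated correlation the adjusted p = 0.606 for each. Satellite and reserve cell markers moved both ways, with 7 of 16 higher and 4 lower (camera adjusted p = 0.483). Myf5, a factor of committed myoblasts, rose 6.96-fold to 57.1 ± 5.14 TPM (adjusted p = 8.02e-07), and the differentiation inhibitor Id3 rose 3.93-fold. Myog stood at 1402 ± 193 TPM against 1330 ± 128 with vehicle (adjusted p = 0.905) and Pax7 at 1.77 ± 0.222 against 1.78 ± 0.503 (adjusted p = 0.877). Mki67 was at 0.403 ± 0.169 TPM against 0.944 ± 0.896 (adjusted p = 0.406).

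For ribosomal proteins and proteasome subunits camera gave a fall, but neither list kept it with an estimated correlation (adjusted p = 0.606 for each). Genes with a mean above 100 TPM were shifted as a whole at 24 h, by a median of −0.11 on the log2 scale of the deposited table and −0.06 by TPM. A fall of abundant lists may therefore not be particular to them, and they were not tested against genes of like abundance. No ribosomal protein gene passed in limma on either table, while 12 of 34 were lower and none higher at an unadjusted p under 0.05 (camera adjusted p = 0.000402). Proteasome subunits had 0 higher and 6 lower of 33, with none in limma adjusted over the list alone, 14 lower at an unadjusted p under 0.05 and 2 lower by TPM (camera adjusted p = 0.00333). Oxidative phosphorylation had 1 higher and 4 lower of 39, or 2 and 3 by TPM (camera adjusted p = 0.0189, adjusted p = 0.606 with an estimated correlation). Autophagy and lysosome genes had 9 of 34 higher and 1 lower at 24 h. At 72 h, with all libraries, they had 3 higher and 5 lower. Proteasome subunits had 3 higher and 0 lower at 72 h, 5 and 0 with the replicate number as a block, or 1 and 0 by TPM. The 24 h response held 4134 genes, 2143 higher and 1991 lower, and 570 differed by at least 1 on the log2 scale. It fell to 2706 genes without dexamethasone 24 h replicate 4 and to 2741 without vehicle 24 h replicate 3. TPM called 3292 genes, 2132 higher and 1160 lower, so the share higher was 64.8% there against 51.8% in the log2 table.

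**Figure D2:**
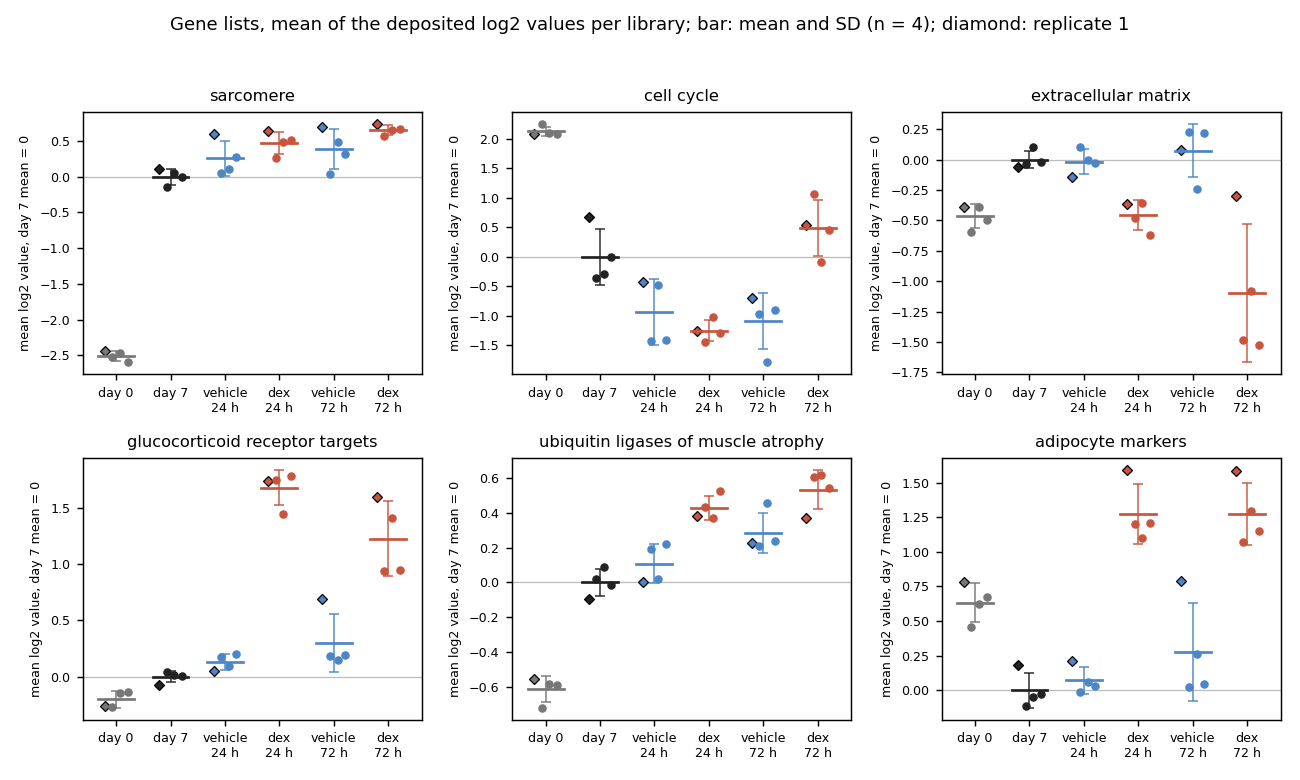
Mean deposited log2 value of the tested genes of 6 lists in each library, relative to the mean of the day 7 myotubes, with 1 point per library and bars for the mean and SD of each group (n = 4). The glucocorticoid receptor targets were higher with dexamethasone at both times, and the cell cycle genes were higher with dexamethasone at 72 h.

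Dexamethasone was compared with vehicle again at 72 h, after sustained exposure and with the same limit on ethanol. Cell cycle genes rose and matrix genes fell. Ccnd1 rose 10.3-fold, from 8.85 ± 6.06 to 91 ± 19.3 TPM (adjusted p = 9.59e-06), and Mki67 rose 7.69-fold, from 0.939 ± 0.651 to 7.21 ± 4.64 TPM (adjusted p = 0.000821). Col3a1, a fibrillar collagen, was 6.7-fold lower at 338 ± 361 against 2266 ± 415 TPM (adjusted p = 2.34e-06), and Igf1 was 19.8-fold lower at 6.66 ± 11.7 against 132 ± 20.5 TPM (adjusted p = 7.11e-07).

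The replicate 1 libraries at 72 h stood apart. Genes near 0 in the other vehicle 72 h libraries were present in vehicle 72 h replicate 1 at a median of 12.8% of their level in dexamethasone 72 h replicate 1. Genes near 0 in the other dexamethasone 72 h libraries were present in dexamethasone 72 h replicate 1 at a median of 19.1% of their level in vehicle 72 h replicate 1. Counts without both libraries (n = 3 and 3) are therefore given beside each group of genes described below at 72 h, and values for part of the genes. Without them Igf1 was at 0.825 ± 0.524 against 139 ± 17.4 TPM, a 169-fold difference, and 4998 genes differed in place of 4931, of which 4423 were called in the same direction in both.

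All 35 cell cycle genes rose at 72 h (camera adjusted p = 4.57e-20, adjusted p = 0.243 with an estimated correlation), and 34 rose without both replicate 1 libraries. The replication helicase subunit Mcm5 rose 10.1-fold (12.8-fold without them) and Ccnd1 16.1-fold without them. Hmga2, a chromatin protein of growing cells, rose 23.6-fold to 187 ± 67.1 TPM (47.6-fold without them).

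Of 32 extracellular matrix genes, 25 fell and 2 rose, with or without both replicate 1 libraries, and 25 of 31 fell and none rose by TPM (camera adjusted p = 4.97e-13, adjusted p = 0.243 with an estimated correlation). Col3a1 was 14.6-fold lower without them, Col1a1 6.68-fold lower (23.5-fold without them) and Timp3 18.3-fold lower (40.9-fold without them). Fibroblast and tendon markers fell alongside, 7 of 11 lower and 1 higher in either set of libraries (camera adjusted p = 0.000324, adjusted p = 0.243 with an estimated correlation). Mfap5 was 4.68-fold lower and Cd248 4.14-fold lower, or 5.93-fold and 7.69-fold without both replicate 1 libraries. TGF-beta signalling had 5 of 21 higher and 12 lower in either set (camera adjusted p = 0.117), with the ligand Tgfb2 2.65-fold lower (3.11-fold without them).

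Glucocorticoid receptor targets had 17 of 30 higher and 3 lower, or 21 and 3 adjusted over the list alone, and 16 and 4 without both replicate 1 libraries (camera adjusted p = 6.35e-08, adjusted p = 0.243 with an estimated correlation). Fkbp5 rose 9.46-fold to 149 ± 32.4 TPM (12.6-fold without them) and Tsc22d3 rose 6.68-fold (8.21-fold without them). Klf15 rose 3.94-fold to 5.34 ± 3.19 TPM (adjusted p = 0.00218), and 3.4-fold without them (adjusted p = 0.0145). Nr3c1 was 1.6-fold lower at 23.6 ± 2.38 against 37.9 ± 7.05 TPM (adjusted p = 0.000496, 1.72-fold without them). Hsd11b1, which reactivates glucocorticoids, was 4.02-fold lower (5.26-fold without them), within a list of steroid handling genes with 3 higher and 3 lower in either set (median 0.06, mean −0.1, camera adjusted p = 0.891 for a fall). Ubiquitin ligases had 9 of 20 higher and none lower, or 10 and 1 adjusted over the list alone, and 10 and 0 without both replicate 1 libraries (camera adjusted p = 0.00739, adjusted p = 0.447 with an estimated correlation). Fbxo32 was 1.99-fold higher at 64.8 ± 11.9 TPM (adjusted p = 0.000444) and Trim63 1.81-fold higher at 83.1 ± 20.4 TPM (adjusted p = 0.000274), or 2.12-fold and 2.01-fold without them. Adipocyte markers had 4 of 10 higher and none lower in either set, with Fabp4 at 75.2 ± 11.9 TPM against 2.15 ± 3.99, and against 0.157 ± 0.0135 without vehicle 72 h replicate 1 (camera adjusted p = 0.00128, adjusted p = 0.243 with an estimated correlation).

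Sarcomere genes had 12 of 44 higher and 3 lower, or 14 and 3 adjusted over the list alone, 18 and 2 without both replicate 1 libraries, 19 and 3 with the replicate number as a block, and 7 and 3 by TPM (camera adjusted p = 0.00359, adjusted p = 0.789 with an estimated correlation). Tnnt2, the cardiac and embryonic troponin T, rose 1.8-fold and Myot, a Z-disc protein, 5.31-fold (1.96-fold and 7.97-fold without them), while the embryonic myosin Myh3 was 1.66-fold lower (1.68-fold). Excitation-contraction coupling had 7 of 23 higher and 1 lower, 9 and 1 without them, and 4 and 1 of 22 by TPM, with the calcium pump Atp2a1 2.18-fold higher, or 2.45-fold (camera adjusted p = 0.0127, adjusted p = 0.76 with an estimated correlation). Heat shock genes had 8 of 15 higher and none lower in either set, the small chaperone Hspb1 2.26-fold and mitochondrial Hspd1 1.69-fold, or 2.46-fold and 1.72-fold without both replicate 1 libraries (camera adjusted p = 2.24e-05, adjusted p = 0.099 with an estimated correlation). Glycolysis and glycogen genes had 11 of 25 higher and 1 lower, or 12 and 1 adjusted over the list alone, and 9 and 0 without both replicate 1 libraries. The glucose transporter Slc2a1 rose 1.91-fold, or 1.94-fold without them (camera adjusted p = 0.00084, adjusted p = 0.447 with an estimated correlation). Myf5 rose 6.01-fold (7.46-fold without them), Pax7 was 2.73-fold lower (3.93-fold), and the satellite and reserve cell list had 4 of 16 higher and 6 lower, or 4 and 7 without them (camera adjusted p = 0.521). Myog was at 1159 ± 337 TPM against 1255 ± 185 with vehicle (adjusted p = 0.595).

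At 72 h 2466 genes were higher and 2465 lower, 964 of them by at least 1 on the log2 scale. TPM called 4056, 1752 higher and 2304 lower. Gene calls at 24 h and 72 h overlapped, with 842 genes higher at both times where independent lists would share 325, and 964 lower at both where 302 would be shared. Opposite calls numbered 57 and 68. Across the 16257 genes the effects at both times had Pearson r = 0.48 and Spearman rho = 0.39. Genes are not independent replicates, and permuting libraries gave p = 0.2286 (adjusted p = 0.3429 over 3 correlations). Splits that exchange 1 library keep part of the effect, and r does not depend on its size. The highest other split reached 0.61, so this test does not decide whether a response was shared. The same limit applies to the correlations with differentiation. The 72 h effect and differentiation had r = −0.4 and rho = −0.34 (permutation p = 0.1429, adjusted p = 0.3429), and the 24 h effect and differentiation r = −0.08 and rho = −0.08 (permutation p = 0.5143, adjusted p = 0.5143). Of the 2466 genes higher at 72 h, 1519 had been lower in myotubes than in myoblasts, where independent lists would share 734.

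The difference between the responses at 72 h and 24 h was tested as an interaction, which called 1842 genes, 904 with a higher and 938 with a lower response at 72 h. It called 2466 without both 72 h replicate 1 libraries, 1730 of them the same in gene and direction. Cell cycle genes had 33 of 35 with a higher response at 72 h, and 33 without both libraries (camera adjusted p = 1.24e-27, adjusted p = 0.318 with an estimated correlation). The response of Ccnd1 was higher by 2.77 on the log2 scale (adjusted p = 0.00091) and that of Mki67 by 2.62 (adjusted p = 0.00763). Glucocorticoid receptor targets had 1 higher and 13 lower of 30, or 1 and 20 adjusted over the list alone, and 2 and 15 without both libraries (camera adjusted p = 3e-08, adjusted p = 0.318 with an estimated correlation). Klf15 differed by −2.22 (adjusted p = 0.00183), whereas Fkbp5 differed by −0.4 (adjusted p = 0.316) and Trim63 by −0.05 (adjusted p = 0.894). Extracellular matrix genes had 1 higher and 12 lower of 32, or 1 and 17 adjusted over the list alone, 1 and 21 without both libraries, and 2 and 16 with the replicate number as a block (camera adjusted p = 1.59e-06, adjusted p = 0.486 with an estimated correlation). Postn went from a rise at 24 h, at 2029 ± 329 against 868 ± 276 TPM, to a fall at 72 h, at 229 ± 208 against 816 ± 255 TPM (difference −2.38, adjusted p = 0.000856). Heat shock genes had 5 higher of 15, 9 adjusted over the list alone, 3 without both libraries and 1 by TPM (camera adjusted p = 0.000169, adjusted p = 0.241 with an estimated correlation).

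Few genes differed between vehicle-treated myotubes at 24 h and day 7 myotubes, a comparison in which vehicle, medium change and the added day cannot be told apart. Asb2, a ubiquitin ligase subunit, was 2.35-fold higher and Lmod2, a thin-filament protein, 1.57-fold higher (both adjusted p = 0.0472), while Cip2a, an inhibitor of a phosphatase, was 3.54-fold lower (adjusted p = 0.0472). In all 34 genes passed, 16 higher and 18 lower, with 2555 at an unadjusted p under 0.05, and TPM called 4. As a list, cell cycle genes were lower by a median of −1.05 on the log2 scale (camera adjusted p = 4.28e-23, adjusted p = 0.468 with an estimated correlation). None of the 35 passed over all genes in limma or by TPM, and 32 were lower adjusted over the list alone, as many as at an unadjusted p under 0.05. Sarcomere genes had 10 of 44 higher adjusted over the list alone and cholesterol synthesis genes 10 of 20 lower (camera adjusted p = 1.73e-10 and 2.13e-10, adjusted p = 0.468 with an estimated correlation for each). No member of either list passed over all genes in limma or by TPM, while 14 in each did at an unadjusted p under 0.05. Each of the 10 named genes called here lost its call under at least 1 of the alternatives. The 34 genes became 0 without day 7 replicate 1, day 7 replicate 4, vehicle 24 h replicate 2 or vehicle 24 h replicate 4, 4 without day 7 replicate 3, 188 without vehicle 24 h replicate 1 and 328 without vehicle 24 h replicate 3.

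Between 24 h and 72 h in vehicle, 709 genes changed, 434 higher and 275 lower, 17 of them by at least 1 on the log2 scale. Akr1c14, an aldo-keto reductase, was 2.89-fold higher at 72 h (adjusted p = 0.0268), the intermediate filament gene Synm 2.58-fold higher (adjusted p = 0.0196) and Nr3c1 1.55-fold higher at 37.9 ± 7.05 TPM (adjusted p = 0.0367), while Igfbp2, a binding protein of insulin-like growth factors, was 2.81-fold lower (adjusted p = 0.0477). Ribosomal proteins had 1 of 34 lower, and 30 adjusted over the list alone (camera adjusted p = 7.33e-14, adjusted p = 0.535 with an estimated correlation), while genes above 100 TPM as a whole were shifted by a median of −0.1 in the deposited table. The count fell to 2 genes without vehicle 24 h replicate 3, 5 without vehicle 72 h replicate 3, 19 without vehicle 24 h replicate 1, 36 without vehicle 72 h replicate 2, 88 without vehicle 72 h replicate 1 and 388 without vehicle 24 h replicate 4, and rose to 1751 without vehicle 24 h replicate 2. All 27 named genes called lost their call under at least 1 of the alternatives. TPM called 270 genes and showed a median shift of 0.14 on the log2 scale.

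Myosin heavy chain composition moved from the embryonic Myh3 toward the adult fast isoform Myh1 and the perinatal Myh8. From day 0 to day 7 the Myh3 share of the summed TPM of 6 isoforms fell from 57% ± 5.38 to 37.6% ± 1.37 and the Myh1 share rose from 30.7% ± 5.13 to 43.3% ± 1.62. Of the 6 shares, 5, those of Myh1, Myh2, Myh3, Myh4 and Myh8, had an exact permutation p = 0.0286 (adjusted p = 0.0343), the smallest the design allows. From day 7 to vehicle 24 h the Myh3 share fell to 29.1% ± 2.63 and the Myh1 share rose to 48.3% ± 1.35, and by vehicle 72 h the Myh3 share was 16.8% ± 3.12 and the Myh8 share 14.9% ± 0.751 (exact permutation p = 0.0286, adjusted p = 0.0429 for each, 4 of 6 shares in each comparison). Without any 1 of the day 7 libraries no share passed in either comparison that uses them, and the same held for vehicle 24 h libraries in the later comparison. With 1 library left out a share fails once any other of the 35 splits is as large, so this does not show dependence on a library. With dexamethasone the Myh3 share was 19.4% ± 3.84 at 24 h and 8.43% ± 1.19 at 72 h, below every vehicle library each time, but the exact permutation p = 0.0286 did not pass after adjustment (adjusted p = 0.0571 and 0.0857). Within the pairs of same-numbered libraries the difference in the Myh3 share ran from −10.8 to −7.84 points at 24 h and from −11.3 to −4.64 at 72 h. That of Myh1 at 24 h ran from 6.26 to 7.35 points and that of Myh8 at 72 h from 2.57 to 4.49. With 4 pairs an exact permutation of signs gives no p below 0.125, so no share can pass in a paired test, those of differentiation included. Reads are divided uncertainly between these related genes, and shares from the log2 table on its linear scale gave 0 passing in differentiation.

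**Figure D3:**
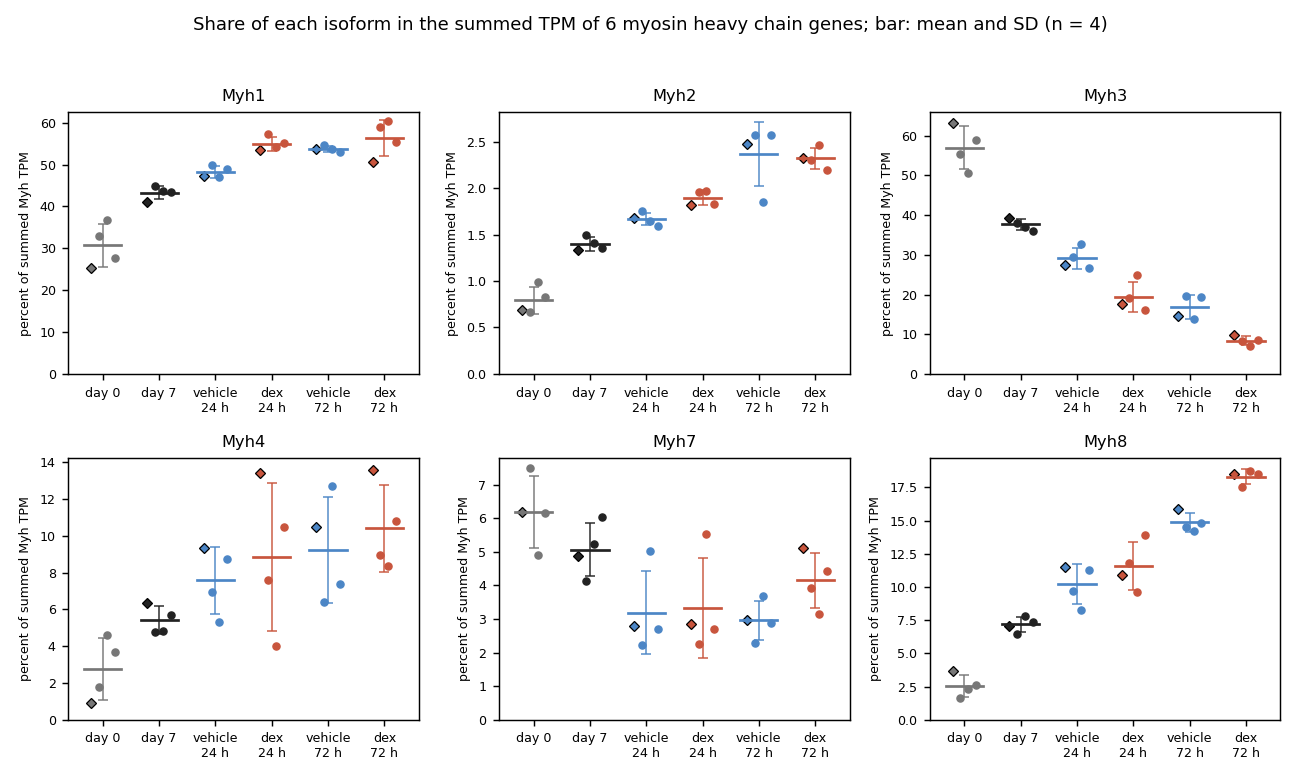
Percent of the summed TPM of 6 myosin heavy chain genes taken by each, in every library. The Myh3 share averaged 57% in day 0 myoblasts, 37.6% at day 7, 16.8% with vehicle at 72 h and 8.43% with dexamethasone at 72 h.

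Mitochondrially encoded transcripts took 7.99% ± 0.475 of TPM in day 7 myotubes and 8.32% ± 0.616 in myoblasts (exact permutation p = 0.4286). The share was 9.15% ± 1.1 with dexamethasone and 7.99% ± 1.66 with vehicle at 24 h (exact permutation p = 0.2857), and 11.5% ± 1.66 and 11.3% ± 3 at 72 h (exact permutation p = 0.8857).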

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

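The tests of shared material and of swapped labels at 72 h were chosen only after the libraries had been seen to stand apart, and leaving out both 72 h replicate 1 libraries was an alternative chosen after the data were seen. Also chosen after the values were seen were the test on myoblast genes without a role in cell division, with the choice of these genes, and the test of the receptor gene level. A single library was picked out where its gap to the nearest library of its group of 4 was large for the range of the group (above Dixon's critical value for 4 libraries). Chance alone picks out about 1 in 20 groups. Of 586 groups of 4, 56 held such a library, 22 of these in a 72 h replicate 1 library and 33 in any replicate 1 library. Part of the named genes were also picked out where the responses to dexamethasone at 72 h and at 24 h differed in the test of that difference.

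The vehicle 72 h replicate 1 library held transcripts otherwise typical of dexamethasone, and the dexamethasone 72 h replicate 1 library held transcripts typical of vehicle. Exchanged labels are argued against, since the mean log2 level of the glucocorticoid receptor targets was still 0.91 higher in the dexamethasone 72 h replicate 1 library, while the other 3 vehicle 72 h libraries spanned 0.04. A share of the other library's material may account for both libraries: 12 genes near 0 in the other vehicle libraries stood at a median of 12.8% of the dexamethasone library, with an upper quartile 1.23 times the lower, and 7 genes stood at a median of 19.1% the other way, with a quartile ratio of 1.21. The highest median of any other library was 6.45%, in dexamethasone 72 h replicate 3, when the replicate 1 libraries were kept out of the choice of genes; with them in, few genes were left, and 3 genes stood at a median of 48.9% in that library and 1 gene at 42.6% in vehicle 72 h replicate 3. Of the 12 genes, 2 lay away from the common share, Mir503 at 0% and Gm43587 at 84.8%, and neither the step at which material was shared nor a biological explanation was tested.

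Of 35 cell cycle genes, all were higher with dexamethasone at 72 h, 2 were higher and 1 lower at 24 h (1 and 2 with the replicate number as a block), and the difference between the responses passed for 33. A fall in the vehicle from 24 h to 72 h is argued against as the source. The dexamethasone 72 h level lay 1.43 above vehicle 24 h on the log2 scale, and vehicle 72 h minus vehicle 24 h was −0.16. Vehicle 24 h was itself low, with 32 of the 35 genes below day 7 at an unadjusted limma p under 0.05. The dexamethasone 72 h level was drawn relative to day 7 but not tested against it. Mki67 was at 3.43 ± 2.42 TPM at day 7 and 0.944 ± 0.896 in vehicle 24 h. With dexamethasone at 72 h it was at 7.19 ± 5.68 TPM without replicate 1 (n = 3). Cip2a, outside the list and named for its fall after day 7, was at 8.88, 2.51 and 10.9 TPM in day 7, vehicle 24 h and dexamethasone 72 h. A vehicle level lowered since day 7 therefore stays open as a part of the difference. Undifferentiated myoblasts with the transcripts of day 0 are argued against as the whole source: the cell cycle genes would need a median share of 19%, and 104 other genes high in day 0 myoblasts and near 0 in vehicle 72 h stood at a median of 16.1%, but most of these are genes of dividing cells, and the 15 picked for having no role in cell division stood at a median of 3.83% (upper quartile 7.86%). By library their median ran from 0.987% (replicate 1, cell cycle genes 16.5%) to 7.32% (replicate 2, 34%), and Igfbp2 stood at −1.42%, Ptn at −3.25%, Sprr1a at 0.195%, Prl2c2 at 5.3%, Nefl at 6.59% and Plaur, the highest, at 23.6%. Cycling of cells under dexamethasone, or myoblasts whose other transcripts had changed, was not tested and stays open.

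Part of the glucocorticoid receptor targets responded less at 72 h than at 24 h, with 13 of 30 lower and 1 higher in the test of the difference, and as a list they did not pass with an estimated correlation (adjusted p = 0.318). The shared material of the replicate 1 libraries is argued against as the whole source, since the median difference between the responses was −0.66 without both libraries and −0.73 with them, and 15 targets were then lower and 2 higher. Fewer transcripts of the receptor gene are argued against too, since Nr3c1 under dexamethasone stood at 72 h at 0.92 of its 24 h level (23.6 ± 2.38 against 25.6 ± 2.64 TPM, n = 4 and 4). The lower value against vehicle at 72 h went with a vehicle level of 24.5 TPM at 24 h and 37.9 TPM at 72 h. That difference between the vehicle times (limma adjusted p = 0.0367) did not keep its call under every alternative. Without both replicate 1 libraries, the 72 h over the 24 h response of the 25 targets higher at 24 h ran from −1.04 for Pik3r1 to 1.53 for Zbtb16, with Fkbp5 at 0.91 and Klf9 at 0.24. Choosing targets by their 24 h response, which is also the divisor, by itself favours ratios below 1. Time in culture and the duration of exposure are confounded here, and receptor protein and feedback on single targets were not tested.

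In the vehicle 72 h replicate 1 library the mean log2 level of the receptor targets was 0.687 relative to day 7, and Tsc22d3 (108 TPM), Serpina3n (25.3), Fabp4 (8.14), Serpinb2 (3.48), Ifi207 (3.17), Sult1a1 (1.92), Slc10a6 (0.95), Lcn2 (0.631), Zbtb16 (0.412) and Slco4a1 (0.319) stood above the other 3 libraries, while Csf2rb was at 2.4 TPM. In the dexamethasone 72 h replicate 1 library Timp3 (49.4 TPM), Igf1 (24.2), Igfbp4 (13.8), Adamts16 (3.4), Dpt (0.871), Lum (0.585), Csf2rb (0.481) and Megf6 (0.312) stood apart, as did Atp2a1 (1061) and S100a8 (14.4). Day 7 replicate 1 stood apart with Fgfbp1 at 50.9 TPM, Sprr1a at 1.2, Myf5 at 20.7, Cdc6 at 2.59, Loxl2 at 5.54, Col6a3 at 58.8 and Mfap5 at 147. Vehicle 24 h replicate 1 did so with Dynap at 46.9, Cd7 at 1.72 and Olfr523 at 0.226 TPM, and day 0 replicate 1 with Fgfbp1 at 0.255 TPM. Day 0 replicate 2 had a mitochondrially encoded share of 7.4%, a cell cycle level of 2.25 relative to day 7, and Hhip at 2.67, Ngfr at 0.645, Nr3c1 at 22.4 and Spry1 at 1.74 TPM. Day 0 replicate 3 had Casq1 at 0.815 and Colq at 0.132 TPM, and day 7 replicate 2 had Myh7 at 14.4 TPM. Dexamethasone 24 h replicate 3 had a receptor target level of 1.45, Tsc22d3 at 503, Asb2 at 16.8, Ppargc1a at 0.577 and C3 at 0.173 TPM. Vehicle 24 h replicate 2 had Ch25h at 8.13 TPM, and vehicle 24 h replicate 3 had Ccn2 at 50.1 and Tgfbr1 at 6.62 TPM. At 72 h, vehicle replicate 2 had Hspb1 at 456 TPM, vehicle replicate 3 Col1a1 at 113 TPM and a Myh2 share of 1.85%, vehicle replicate 4 Cpt1b at 0.704 TPM, dexamethasone replicate 2 a Myh8 share of 17.5% and dexamethasone replicate 3 Ccn2 at 609 TPM.

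Log2 differences between the dexamethasone responses, 72 h minus 24 h, passed for 74 of the named genes. Of these 26 are given here, a part chosen after the values were seen. They were 4.67 for Serpinb2, 3.43 for the acyl-CoA synthetase Acsbg1, 3.42 for Il18rap and 3.27 for Prl2c2. Genes of dividing cells had 3.34 for Pclaf, 2.8 for Cdc6, 2.77 for Ccnd1, 2.76 for Mcm5, 2.63 for Bub1 and 2.62 for Mki67. Among the glucocorticoid receptor targets, Klf15 had −2.22, Rgcc −1.53 and Cebpd −1.35, while Angptl4 went the other way with 1.4. The largest negative differences were −3.53 for Scara5, −3.46 for Lbp, −3.25 for Adamts15, −3.08 for Ism1 and −3.07 for Crispld2, and matrix genes had −2.38 for Postn, −1.7 for Col6a1 and −1.68 for Mmp2. Others were −1.97 for Igf1, −0.94 for Pax7, −0.72 for Fbxo32 and −0.44 for Nr3c1.

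Several of these calls lay near the threshold and did not pass when 1 library was left out, where fewer libraries are part of the setting. Igf1 had an adjusted p of 0.0546 without dexamethasone 72 h replicate 2 and 0.0554 without dexamethasone 72 h replicate 4, with differences of −1.75 and −1.69, and Col6a1 0.0545 and 0.0516 with −1.45 and −1.39. Nr3c1 had 0.053 and 0.0619 without those libraries, 0.0588 without vehicle 24 h replicate 3 and 0.0612 without vehicle 72 h replicate 2, with differences of −0.42 to −0.36. Fbxo32 had 0.0576 without dexamethasone 24 h replicate 4, 0.0542 without dexamethasone 72 h replicate 4, 0.0559 without vehicle 24 h replicate 3, 0.0534 without vehicle 72 h replicate 3 and 0.0547 without both 72 h replicate 1 libraries, with differences of −0.68 to −0.59. Crispld2 had 0.0704 and 0.0564 without dexamethasone 24 h replicates 1 and 3, 0.0593 and 0.0513 without vehicle 24 h replicates 1 and 4, 0.0723 without vehicle 72 h replicate 1, and 0.0884, 0.0541 and 0.0869 without dexamethasone 72 h replicates 2, 3 and 4, with differences of −3.06 to −2.59. Pax7 had 0.067, 0.073 and 0.0526 without dexamethasone 24 h replicates 1, 2 and 4, 0.0779, 0.0517 and 0.0976 without dexamethasone 72 h replicates 2, 3 and 4, 0.0875 and 0.0603 without vehicle 24 h replicates 3 and 4, and 0.0521 and 0.092 without vehicle 72 h replicates 1 and 2, with differences of −0.98 to −0.74. Angptl4 had 0.0784, 0.0621, 0.0621 and 0.0635 without vehicle 24 h replicates 1 to 4, 0.0688, 0.101 and 0.0504 without vehicle 72 h replicates 2, 3 and 4, and 0.109 and 0.0815 without dexamethasone 72 h replicates 2 and 4, with differences of 1.2 to 1.46. Tsc22d3 had a difference of −0.51 that did not pass (adjusted p = 0.0622), and it passed without vehicle 24 h replicate 1 (0.0287), dexamethasone 24 h replicate 3 (0.0268), vehicle 72 h replicate 2 (0.0475) or vehicle 72 h replicate 4 (0.0448), and with the replicate number as a block (0.029).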

How the results depend on the processing

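Leaving out the replicate 1 libraries, the TPM pseudocount of 1 and sign changes within pairs were chosen after the data were seen. For differentiation, dexamethasone at 24 h and at 72 h and the difference between the responses, the counts of genes stayed within 1.5 times their value under the other filters, quantile normalisation, TPM with either pseudocount, robust empirical Bayes, the fit of the compared groups alone and the libraries left out as a set. Single libraries left out gave 9023 to 9604 genes for differentiation, 2706 to 4358 for dexamethasone at 24 h, 3892 to 5472 at 72 h and 1241 to 2686 for the difference, and only at 24 h did this move a count by over 1.5 times. The fits to counts and the pseudocounts for counts were not run, because the deposited values are not counts.

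The 34 genes between vehicle 24 h and day 7 became 4 with no filter, 4 with TPM, 5 with TPM and a pseudocount of 1, 0 without all 6 replicate 1 libraries, 0 in a fit of the compared groups alone and 0 to 328 with single libraries left out. The 709 genes between the vehicle times became 94 with no filter, 270 with TPM, 264 with a pseudocount of 1, 380 without both 72 h replicate 1 libraries, 5 without all 6, 4 in a fit of the compared groups alone and 2 to 1751 with single libraries left out. The cause was not tested. A larger number of genes tested is part of the setting without a filter, and fewer libraries part of the others.

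Camera called 10 lists for differentiation, 12 for dexamethasone at 24 h, 12 at 72 h, 13 for the difference between the responses, 10 for vehicle 24 h against day 7 and 13 between the vehicle times. With an estimated correlation these became 0, 1, 0, 0, 0 and 0. Fry, which asks whether a list's genes move one way and not whether they move more than others, gave 22 for differentiation, 7 for the difference, 0 for vehicle 24 h against day 7 and 5 between the vehicle times. Single libraries left out lowered the lists for vehicle 24 h against day 7 to 6 at the least, and the highest was 11. Myosin shares that passed went from 5 to 0 in differentiation with shares from the log2 table on its linear scale, and single libraries left out gave 0 to 5 there, 0 to 6 for vehicle 24 h against day 7 and 0 to 4 between the vehicle times. The difference in mitochondrially encoded share in differentiation, −0.33 points, became 0.144 with shares from the log2 table, and neither passed. With 1 library left out a myosin share fails once any other of the 35 splits is as large. The cause of the changes was not otherwise tested.

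With the number as a replicate block the counts were 10047, 4621, 5433 and 2233 for the first 4 comparisons. Among the lists of these, extracellular matrix lost its call in differentiation and satellite cell markers gained one, as did myogenic regulators and smooth muscle markers at 24 h. Among the named genes Psmb6 and Mcm7 at 24 h lost their calls (adjusted p = 0.0557 and 0.0554), while Tsc22d3 in differentiation (0.0318), Ckm at 24 h (0.0267), Myh7 at 72 h (0.00988), and Myh3 (0.0445), Lpl (0.0199), Smtn (0.0358) and Tsc22d3 in the difference between the responses gained one. Sign changes within pairs took the myosin shares that passed in differentiation from 5 to 0, since 4 pairs are too few. Calls shared with the fit without a block numbered 9724 in differentiation, 4071 at 24 h, 4879 at 72 h and 1809 in the difference. In the comparisons of vehicle groups not every pair of same-numbered libraries correlated, so the numbers were not taken to pair them. This does not show that those libraries are unpaired. The counts with the block were 109 and 1067 there. Sarcomere genes then passed as a list between the vehicle times (camera adjusted p = 0.0483). Without the block no list of that comparison passed with an estimated correlation, and both together were not tested. As a hint from the data alone, 16 of the 24 libraries were closest to a library of their own number.

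Of all genes that the rule for named genes took and that were called, 137 of 147 kept their call under every alternative run in differentiation, 92 of 124 at 24 h, 102 of 122 at 72 h, 40 of 74 in the difference between responses, and 0 of 10 and 0 of 27 in the comparisons of vehicle groups. Only a part of these genes, chosen after the values were seen, is followed in the text. None of them reversed. Depth is unknown, so whether it limited the genes at low levels cannot be read from these tables.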

Other observations

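The regroupings of libraries were planned, except those limited to splits that part every pair of same-numbered libraries, while the within-group component and the gene Gm15662 were singled out only after the values were seen. With dexamethasone, the clock genes Per3 and Dbp fell at both times. The related gene Per1, counted with the receptor targets and not in the circadian list, went the other way. Its log2 difference was 1.3 at 24 h and 1 at 72 h without both 72 h replicate 1 libraries. Per3, a period gene, was 3.53-fold lower at 24 h (1.65 ± 0.345 against 5.82 ± 0.873 TPM, n = 4, adjusted p = 6.38e-08) and 3.57-fold lower at 72 h (adjusted p = 1.97e-07), or 4.14-fold without both 72 h replicate 1 libraries. Dbp, a clock-controlled transcription factor, was 2.96-fold lower at 24 h and 4.02-fold lower at 72 h (adjusted p = 3.31e-06 and 3.77e-07), or 4.43-fold without them, while Clock was 1.68-fold higher at 24 h. The circadian list had 2 of 16 higher and 6 lower at 24 h, or 2 and 3 of 15 by TPM (camera adjusted p = 0.0832), and 3 higher and 7 lower at 72 h, or 3 and 8 without both replicate 1 libraries (camera adjusted p = 0.0324, 0.0885 with TPM, and adjusted p = 0.447 with an estimated correlation). Cholesterol synthesis genes had 1 of 20 higher and 3 lower at 24 h, or 0 and 3 adjusted over the list alone, Cyp51 1.69-fold lower (camera adjusted p = 0.00636, adjusted p = 0.606 with an estimated correlation). At 72 h they had 0 higher and 1 lower with or without both libraries (camera adjusted p = 0.301).

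At 72 h, among 20 xenobiotic and oxidative stress genes, 9 rose and 1 fell, or 9 and 2 adjusted over the list alone, and 9 and 3 without both 72 h replicate 1 libraries (camera adjusted p = 0.0324, 0.0505 after quantile normalisation, and adjusted p = 0.514 with an estimated correlation). The quinone reductase Nqo1 rose 3.08-fold and Gclm, a subunit of the glutathione-synthesis enzyme, 2-fold (adjusted p = 0.007 and 4.68e-06). At 24 h that list had 7 higher and 2 lower (camera adjusted p = 0.152), with Gstm1, a glutathione transferase, 2.96-fold higher. The integrated stress response list had 6 of 19 higher and 1 lower at 72 h in either set of libraries (camera adjusted p = 0.146), including the serine synthesis genes Phgdh, 1.99-fold, and Psat1, 1.89-fold (adjusted p = 0.000565 and 0.00019). Fatty acid oxidation genes had 6 of 21 higher and 3 lower, or 5 and 3 without both libraries (camera adjusted p = 0.446), with the fatty acid transporter Cd36 3.19-fold (4.1-fold without them) and Cpt1b, the muscle carnitine transferase, 3.18-fold higher (3.6-fold), and the uncoupling protein gene Ucp2 2.62-fold lower. Insulin and IGF signalling had 7 of 24 higher and 5 lower in either set, or 4 and 5 by TPM (camera adjusted p = 0.653), with a median of 0.11 and a mean of −0.2 on the log2 scale.

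Other splits of the 8 libraries of a comparison were tested for the counts of genes. For differentiation 1 of 35 splits, the real one, gave as many as 9797 genes, and the highest other gave 1679, so chance can be excluded there if all splits count alike. The same held for dexamethasone at 24 h, with 1 of 35 and 4134 genes against 6, and at 72 h, with 1 of 35 and 4931 against 2384. That highest other split at 72 h exchanged dexamethasone 72 h replicate 1 with vehicle 72 h replicate 3, and without both 72 h replicate 1 libraries the real split gave 4998 genes. The real split parts all 4 pairs of same-numbered libraries, as do 7 others in each of these comparisons, which gave at most 1 gene for differentiation, 0 at 24 h and 768 at 72 h. The 8 splits are too few for a share under 0.05, and the others leave at least 1 pair on 1 side. Vehicle 24 h against day 7 had 1 of 35 splits with 34 genes, against 4 for the highest other. The vehicle times had 1 of 35 with 709 against 34. This is the smallest share the splits can give, and both counts moved with single libraries. Without all 6 replicate 1 libraries they were 0 and 5, so chance is not excluded for them. For the difference between the responses, 3 of 100 drawn splits gave as many as the real 1842 genes, so that chance can be excluded at a share under 0.05 if all splits count alike. The highest other, 3194 genes, had 3 libraries exchanged at 24 h and 0 at 72 h, which is close to the mirror of the 24 h groups and so tests nearly the sum of the responses, and the other, 1848 genes, had 2 libraries exchanged at 72 h. Among 100 drawn splits that part every pair, 8 gave as many, so chance is not excluded by that count. The highest, 6357 genes, had 0 libraries exchanged at 24 h and 4 at 72 h, the mirror of the 72 h groups, and the other 6 had 3 or 4 exchanged at 1 time, so that they too lie near the sum of the responses.

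Within groups, the leading principal component of the deviations from the group means held 21.5% of their variance. The replicate 1 libraries of the 5 differentiated groups loaded on it with 0.32 to 0.45, day 0 replicate 1 with 0.09 and the other libraries with −0.17 to −0.02. Without all 6 replicate 1 libraries 9417 genes differed in differentiation, 3606 with dexamethasone at 24 h, 5185 at 72 h and 2195 in the difference between the responses. The labels name no batch, so what replicate 1 marks is not given in the sources used here. The vehicle 72 h replicate 3 library had the highest mitochondrially encoded share, 15.5% of TPM. The predicted gene Gm15662 had the highest TPM of any gene in most libraries, for example 41562 in day 7 replicate 1, and varied from 61686 in day 0 replicate 2 to below the level of mt-Atp8 in the other day 0 libraries.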
